A study of Capra hircus with 2 samples.

How the data were processed

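Genomic DNA from pineal glands of female goats (Capra hircus) was spiked with lambda DNA, sheared, bisulfite-converted with a Zymo kit and sequenced in pairs on an Illumina instrument, per the labels' protocols. There were 2 libraries, 1 from prepuberty and 1 from puberty, and the groups were taken from the developmental stage in the labels. Each deposited file has a line per cytosine with its sequence, position, strand, the counts of methylated and unmethylated reads as the authors deposited them, the level, the context and a p-value. The level is deposited as a fraction, methylated reads over all reads at the cytosine, and was recomputed here from the counts. The p-values and adjusted p-values are the authors' own, deposited per cytosine and library. The tools CASAVA, FastQC 0.11.5, fastp 0.20.0, HISAT2 2.0.5 and Bismark 0.16.3 are named per the submitters' processing notes, without their roles or settings. The genome build was not given in the sources used here, and neither were duplicate removal and the conversion rate.

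The files were checked for what they hold. Every listed cytosine had at least 5 reads, a level of at least 5% and an adjusted p of at most 0.00999, so cytosines not called methylated are missing and their levels are unknown. The deposited p-value equalled, within 1% of its size, an upper binomial tail with an error rate that was the same for all cytosines of a library and context, in 100.0% of those examined. For CG, CHG and CHH this rate was 0.416%, 0.407% and 0.401% in the prepuberty file and 0.675%, 0.711% and 0.654% in the puberty file. At 20 reads, a CHG cytosine therefore needed 3 methylated reads to be listed in the prepuberty file and 4 in the puberty file. A listing rule and coverage that differ between libraries affect which cytosines enter a level, so most comparisons used cytosines listed in both files, 82.5% of the prepuberty and 74.6% of the puberty CG cytosines.

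Gene names and neighbours came from a RefSeq table of the goat assembly ARS1.2, which gives no strand, exons or introns. Since no build is named for the files, the fit of the table was checked from the data. Listed CG cytosines were sparser at annotated gene ends than 10000 bp away on 29 of 29 chromosomes, with a ratio of 0.62 to 0.90, against 0.97 to 1.05 after moving the genes by 50000 bp. Positions printed are those of the first and last measured cytosine in the files, and gene assignment carries the limit that the build was inferred. The 19063 protein-coding genes on chromosomes 1 to 29 were used. Promoters had been planned, but without strand the start of a gene is unknown, so both ends of each gene were used in their place, from 1000 bp outside to 500 bp inside the end. Gene bodies ran from 500 bp inside either end. Genes on unplaced sequences were not tested, and exons, introns, CpG islands and repeats were not analysed here.

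Levels were pooled reads over cytosines with at least 5 reads, with exact (Clopper-Pearson) 95% binomial intervals. Single CG cytosines with at least 10 reads in both libraries, 1 kb windows with at least 5 shared cytosines, gene ends with at least 5 and gene bodies with at least 20 were compared by two-sided Fisher's exact test on methylated and unmethylated reads. P-values were Benjamini-Hochberg adjusted over all regions of a kind with a threshold of 0.05, and a minimum difference of 20 points for cytosines and windows and 10 points for gene ends and bodies was required. Reads of a region were summed over its cytosines, so a read that covers several cytosines is counted at each of them. Fisher's test treats all these counts as independent. A second test took the variance of the difference from the spread between cytosines (normal approximation, rough where cytosines are few). Standard errors printed beside gene differences come from that second test. It treats cytosines as independent, although neighbours can share reads, so both tests and the binomial intervals can understate the uncertainty. As a background, the same Fisher's test was run between the strands of 1 library on the 2149573 CG pairs listed on both strands in both libraries. The genome-wide median difference of the windows was 0.192 points. Counted per cytosine in this way, the median gene end held 130 reads in the prepuberty and 135 in the puberty library, and the median gene body 2628.5 and 2762.

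The tests, regions (apart from gene ends in place of promoters), thresholds, gene lists and most alternatives were chosen before the data were examined. The alternatives were other coverage minimums, double the number of cytosines, other minimum differences and window sizes, other reaches of gene ends, leaving out the top 1% of coverage, thinning to the smaller coverage, centring on the median difference and unweighted means. Added after seeing the data were the calling rule matched between libraries, the correction for error rates, non-CG cytosines with at least 20 reads and a level of at least 30%, the test on the spread between cytosines without a minimum difference (also thinned), matching random lists on several properties, single strands, and bins of 100 kb. Adjustment over each list alone was also computed after the other results had been seen.

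Gene lists held 398 entries in 17 lists, of which 359 were found on chromosomes 1 to 29. They covered melatonin synthesis, pineal signalling, photoreceptor identity, the clock, puberty control, steroid hormones, DNA methylation, imprinting, 6 cell types, developmental factors, neurotransmitter receptors and GnRH signalling. A further list of 27 T lymphocyte markers, 1 of which also stood in another list, was chosen after seeing the data. Named genes were fixed by a rule: the 10 genes with a symbol and the largest increases and the 10 with the largest decreases among gene ends past the threshold with at least 10 shared cytosines, 5 and 5 likewise among gene bodies, in each list the members past the threshold or otherwise up to 3 members with the largest end differences, and 9 genes whatever their values. Some genes that this rule takes are not reported here, and the counts include them.

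The procedures were tested on simulated data, drawn at the real cytosines and depths. Reads were drawn independently at each cytosine, from 1 level shared by both libraries where nothing was changed. The listing rule was not applied, and only mostly methylated regions were lowered. Reads shared by neighbouring cytosines and differences between strands are therefore not part of the simulation. Fisher's test with the minimum difference found 23.5%, 72.0% and 84.0% of windows lowered by 20, 30 and 40 points, 11.5%, 53.5% and 86.5% of gene ends lowered by 10, 20 and 30 points, and 50.5% and 100.0% of gene bodies lowered by 10 and 20 points. It called 10 of 1499876 unchanged windows, 18 of 18766 unchanged gene ends and 3 of 12848 unchanged gene bodies. The real data gave larger shares of calls between the strands of 1 library, as given below. These counts are therefore not a rate of false calls in the real data. Without the minimum difference it called 98 unchanged gene bodies, the spread test 68, and the spread test after thinning 9. Of 300 random lists of 15 bodies, 3.3% lay outside the central 95%, and 91.7% lay above it after 1.5 points were added. Gene ends and shorter lists were not tested in this way. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9.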

Results

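Cytosine methylation was measured in the pineal gland, the brain gland that releases melatonin at night, of untreated female goats before and at puberty. Whole-genome bisulfite sequencing was used, in which unmethylated cytosines are converted and read as thymine while methylated cytosines are not. The prepuberty group and the puberty group had 1 library each. Whether a library came from a single animal or from pooled glands was not stated in the labels. Pubertal animals were recognised by an inflamed vulva and mature follicles in the ovary, according to the design text. The comparison asked how methylation of this tissue differed between the stages.

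The prepuberty file listed 18823171 CG, 611896 CHG and 2891186 CHH cytosines (H stands for A, C or T), with 323088820 reads over all of them. The puberty file listed 20828545, 306758 and 2115043, with 331362605 reads. The median listed CG cytosine was covered by 11 reads in the prepuberty library and 10 in the puberty library. Both files list cytosines that had been called methylated, so every level below is a level of listed cytosines, and a cytosine absent from a file was unmethylated, too weakly methylated to be called, or covered by too few reads. No difference below has a replicate check. Fisher's exact test on the reads of these 2 libraries compares those libraries, not the conditions, and the intervals cover counting error only. A read is counted at every listed cytosine it covers, so the counts are not independent. The p-values can therefore be too small and the intervals too narrow.

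CG methylation was slightly higher in the puberty library on all 29 chromosomes. The level over all listed CG cytosines was 80.025% (exact 95% binomial interval 80.02 to 80.03) in the prepuberty library and 80.431% (80.43 to 80.44) in the puberty library, a difference of 0.406 points. Over the 15535315 CG cytosines listed in both libraries, the chromosomes were higher by 0.35 ± 0.10 points (mean ± SD over chromosomes). The smallest difference was 0.18 points on chromosome 5 and the largest 0.57 points on chromosome 19. Among chromosomes 1 to 29, chromosome 29 had the lowest level in both libraries (80.2% and 80.6%), and chromosome 22 the highest (82.5% and 83.0%). These are the autosomes, so the X chromosome is outside the chromosome, 1 Mb bin and gene results. Over all listed CG cytosines, the largest unplaced scaffold was at 65.86% in the prepuberty and 67.23% in the puberty library. The next largest was at 62.89% and 63.97%. What these scaffolds are was not tested. Giving every listed cytosine the same weight instead of weighting by reads lowered the difference to 0.248 points.

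**Figure D1:**
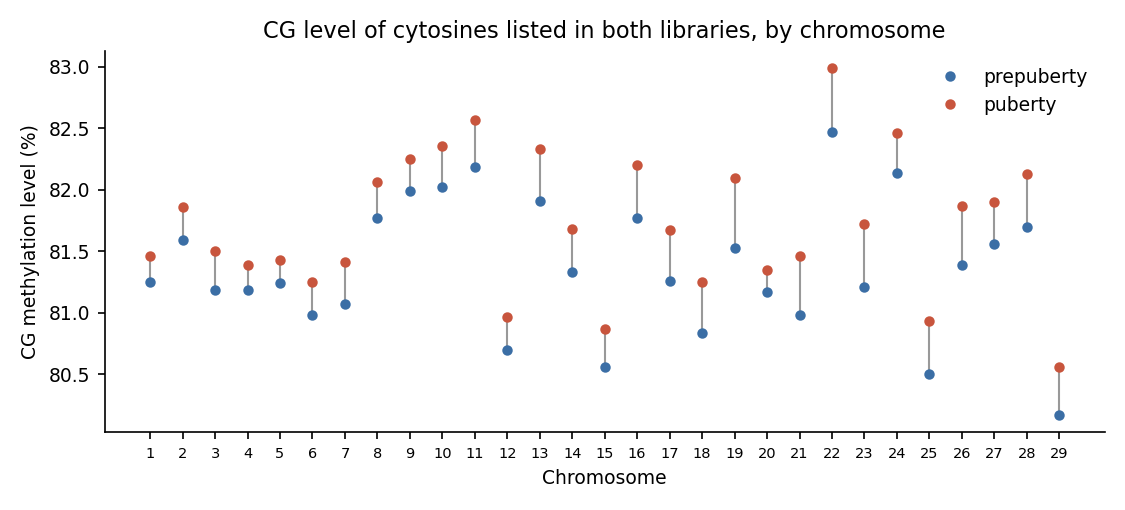
CG methylation level (percent, y axis, not starting at 0) of the cytosines listed in both libraries on chromosomes 1 to 29 (x axis), with prepuberty in blue, puberty in red and a line joining the levels of a chromosome. The puberty point lies above the prepuberty point on all 29 chromosomes, by 0.18 to 0.57 points.

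The difference was larger in gene bodies than between genes. In gene bodies the shared cytosines were at 82.8% in the prepuberty library and 83.3% in the puberty library, 0.503 points higher. At gene ends, which include the promoters, the levels of shared cytosines were 78.5% and 78.9%, a difference of 0.408 points. Cytosines not called methylated are left out, so these are not levels of whole promoters. Between genes they were 80.5% and 80.7%, a difference of 0.205 points. Listed CG cytosines were fewest close to gene ends, with 2.37 per 500 bp just outside an end in the prepuberty library against 3.38 at 10000 bp away, and 2.68 against 3.83 in the puberty library. The differences between genes and in gene bodies were 0.016 and 0.389 points when every cytosine had the same weight. With a correction for each library's error rate as well, chosen after seeing the data, they were -0.032 and 0.347 points.

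**Figure D2:**
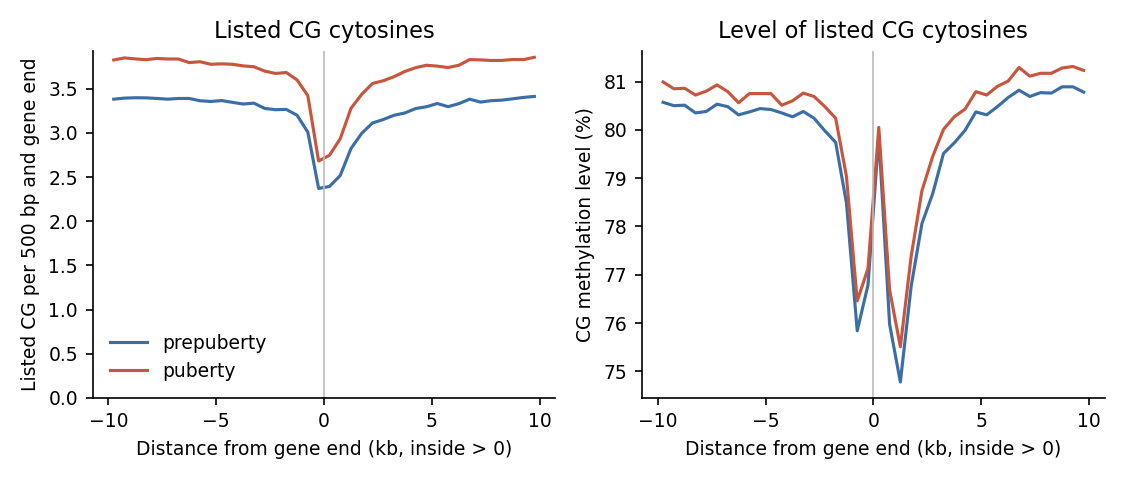
Listed CG cytosines per 500 bp and gene end (left) and their methylation level in percent (right, y axis not starting at 0). The x axis is the distance from each annotated gene end in kb, positive towards the inside of the gene. Prepuberty is in blue and puberty in red. A cytosine near several ends is counted at each, and in short genes the inside distances reach past the other end. Both libraries have fewer listed cytosines around the gene end, 2.37 and 2.68 per 500 bp just outside it.

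Outside the CG context, the puberty file listed fewer cytosines. It held 0.501 times as many CHG and 0.732 times as many CHH cytosines as the prepuberty file. The level of the listed CHG cytosines was 24.2% (24.17 to 24.22) in the prepuberty library and 32.7% (32.62 to 32.70) in the puberty library, and that of CHH cytosines 23.3% (23.33 to 23.35) and 29.2% (29.22 to 29.25). Most deeply covered, strongly methylated cytosines listed as CHG or CHH were listed in both files. Of the CHG cytosines with at least 20 reads and a level of 70% or more, 97.9% of the 7507 in the prepuberty library were listed in both libraries, and of the CHH cytosines 98.1% of 25627. For CG cytosines of that class the share was 99.84%. A deep cytosine at such a level passes either calling rule wherever it is covered. Bases that differ from the reference can make a CG look like a CHG or CHH, which was not tested. The calling rule was stricter in the puberty file, with at least 3 methylated reads at 10 reads of coverage where 2 sufficed in the prepuberty file. Under the stricter rule in both libraries, chosen after seeing the data, the ratios turned to 1.17 for CHG and 1.19 for CHH, and the differences in level to -0.235 points for CHG and 0.646 points for CHH.

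**Figure D3:**
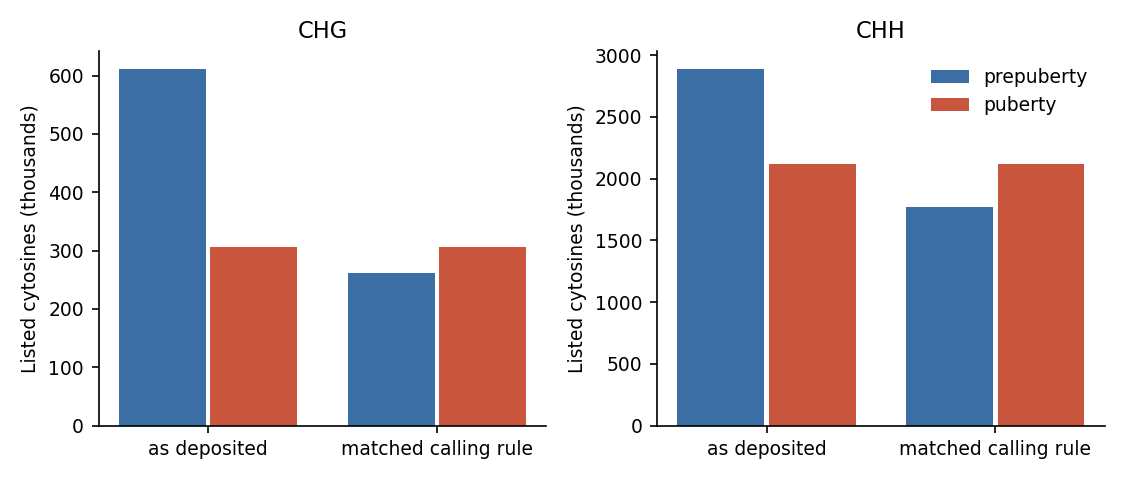
Numbers of listed CHG (left) and CHH (right) cytosines (y axis, in units of 1000) in the prepuberty (blue) and puberty (red) files as deposited and after applying the stricter calling rule to both. The puberty bar is the lower of each pair as deposited (ratios 0.501 and 0.732) and the higher under the matched rule (1.17 and 1.19).

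Differences at single cytosines and in 1 kb windows went in both directions. Of 8559128 CG cytosines with at least 10 reads in both libraries, 12810 were higher and 11840 lower in the puberty library (two-sided Fisher's exact test, Benjamini-Hochberg adjusted, at least 20 points). Of 1500476 windows, 3971 were higher and 2973 lower. Windows inside gene bodies leaned upwards, with 1459 higher and 895 lower, while between genes 2159 were higher and 1905 lower. At gene ends 46 windows were higher and 31 lower, and on sequences not placed on a chromosome 307 were higher and 142 lower. These counts were set beside those between strands. Over the 71432 windows with enough CG pairs listed on both strands, 249 (plus strand) and 203 (minus strand) differed between the libraries, against 373 between the strands of the prepuberty library and 298 between those of the puberty library. Opposite strands of different libraries differed in 697 and 659 windows. With a variance taken from the spread between the cytosines of a window, 525 windows were higher and 306 lower.

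At gene ends, the largest increases with at least 10 shared cytosines included CNOT10, a subunit of the CCR4-NOT complex that shortens mRNA tails, and RAD21L1, a cohesin subunit of meiosis. The end of CNOT10 on chromosome 22 (7008897 to 7009342) was at 26.1% in the prepuberty library and 53.5% in the puberty library, a difference of 27.4 ± 5.56 points (SE from the spread between 12 cytosines, adjusted p = 0.00165, Fisher's exact test). SPRYD7 on chromosome 12 (67196152 to 67197411) was 21.8 ± 4.33 points higher (adjusted p = 0.00113, Fisher's exact test). RAD21L1 was 21.9 ± 11.9 points higher, ODF3L1, related to a protein of the outer dense fibres of sperm tails, 24.0 ± 9.46, and ADCY2, an adenylyl cyclase, which makes cAMP, 19.7 ± 6.10. The ETS-family repressor ETV6 (19.4 ± 8.74), the proton-pump subunit ATP6V1B2 (18.8 ± 5.02), the endothelial lipase LIPG (18.8 ± 8.22), the epidermal transcription factor GRHL3 (18.1 ± 5.66) and the peptidase PGPEP1 (18.0 ± 5.84) followed.

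Among gene ends past the threshold with at least 10 shared cytosines, the largest decrease was at KCTD14 on chromosome 29 (17457363 to 17457957), from 72.7% to 46.7% (-26.1 ± 7.46 points, adjusted p = 0.00165, Fisher's exact test). CCRL2, a receptor-like protein that binds the chemoattractant chemerin, was lower (-20.5 ± 5.91 points), as were C15H11orf91 (-19.7 ± 7.40), the translation factor subunit EIF3J (-19.5 ± 5.42) and the phospholipid-binding protein ANXA5 (-19.4 ± 5.16). MAPK10, a neuronal JNK kinase, had -19.1 ± 6.51 points. RTN4, which encodes the neurite growth inhibitor Nogo, had -19.7 ± 7.39 points in a stretch that also overlaps EML6 and cannot be assigned to either. The matrix metalloproteinase MMP27 (-18.7 ± 9.83), the collagen-binding integrin subunit ITGA2 (-18.1 ± 6.21) and LDLRAD3 (-18.1 ± 4.92) completed the set.

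Of 19447 gene ends tested, 90 were higher and 60 lower by at least 10 points. On the variance from the spread between cytosines, 5 were higher and 2 lower, CNOT10 and SPRYD7 among those higher, and none of the other ends in the preceding lists of increases and decreases passed. After thinning both libraries to the smaller coverage at each cytosine, 16 were higher and 16 lower, and over the 2063 ends with enough CG pairs, 6 and 13 differed between the libraries on the plus and minus strands, against 19 and 15 between the strands within the prepuberty and puberty libraries and 28 and 17 between opposite strands of different libraries.

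The gene bodies with the largest increases past the threshold were those of FHL3 and INA. INA on chromosome 26 (27864811 to 27874776), which encodes the neuronal intermediate filament alpha-internexin, was at 52.4% in the prepuberty library and 68.3% in the puberty library, 15.9 ± 2.85 points higher over 60 cytosines (adjusted p = 2.06e-08, Fisher's exact test). NXNL2, which encodes a photoreceptor survival factor, was 14.4 ± 4.14 points higher, and PDE4C, a phosphodiesterase that breaks down cAMP, 14.0 ± 4.33. FHL3, a LIM-domain protein of muscle, was 16.0 ± 4.18 points higher and the zinc finger gene ZNF653 12.9 ± 3.78.

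Among the gene bodies that were lower, KLHL11 on chromosome 19 (41687346 to 41692396) went from 55.9% to 41.5% (-14.4 ± 2.89 points, adjusted p = 3.87e-05, Fisher's exact test). MAFG, a small MAF transcription factor, had -14.6 ± 4.45 points, and TSPO, a protein of the outer mitochondrial membrane, -13.6 ± 4.22. LHX5, a LIM-homeobox factor of the developing forebrain, had -12.1 ± 2.70 points and SEC61A1, a subunit of the channel for proteins entering the endoplasmic reticulum, -11.4 ± 4.24. With the variance from the spread between cytosines, 9 of these 10 named bodies stayed past the threshold and SEC61A1 did not.

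Of 13480 gene bodies, 26 were higher and 16 lower by at least 10 points. Thinning both libraries to the smaller coverage turned the balance to 7 higher and 12 lower. Over the 7038 bodies with enough CG pairs, 11 and 7 differed between the libraries on the plus and minus strands, against 38 and 44 between the strands within the prepuberty and puberty libraries and 61 and 65 between opposite strands of different libraries. With no minimum difference, 1476 bodies were higher and 294 lower, and 685 and 88 on the spread between cytosines, an alternative chosen after seeing the data. In simulated data with independent cytosines the latter test called 68 of 12848 unchanged bodies.

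Genes of melatonin synthesis were compared next, since melatonin is the hormone of this gland. Counts adjusted over the list alone, given here and for each list that follows, were added after the other results had been seen and are not corrected across the 17 lists. None of the 10 measured gene ends of this list passed the threshold over all ends tested, and 3 were higher and 0 lower when adjusted over the list alone. The higher ones were GCH1, which makes the cofactor of tryptophan hydroxylase (SE of the difference 9.18 points, adjusted p = 0.0889 over all ends and 0.00787 over the list, Fisher's exact test), TPH1, the tryptophan hydroxylase of the pineal gland (18.1 ± 7.11 points, adjusted p = 0.0956 and 0.00787), and DDC, the decarboxylase of the next step (12.8 ± 4.81 points, adjusted p = 0.202 and 0.028). Their levels went from 46.7% to 76.7%, from 54.2% to 72.4% and from 59.1% to 71.9%. In the same order they rested on 7, 12 and 5 cytosines, with 60 reads counted over them in each library at GCH1. The body of TPH1 on chromosome 15 was at 77.2% and 76.3% and its other end at 88.6% and 87.0%, neither past the threshold. AANAT, the acetyltransferase that sets the daily melatonin rhythm, had 80.4% and 91.3% at the measured end (adjusted p = 0.633, Fisher's exact test), where it overlaps RHBDF2. AANAT has another entry in the annotation, so its values are uncertain, and ASMT, the last enzyme of the pathway, was not placed on a chromosome and was not analysed here.

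Among 16 ends of pineal adrenergic and cAMP signalling genes, ADCY2 was higher and none lower over all ends. Adjusted over the list alone, 1 was higher and 2 lower. CREM, a cAMP-responsive transcription factor chosen after its values were seen, was among the lower ones (-10.9 ± 3.38 points, adjusted p = 0.0108 over the list, Fisher's exact test). The body of ADCY2 differed by 1.45 ± 0.35 points, below the minimum of 10.

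None of 38 ends of puberty and gonadotropin control genes passed over all ends, and 1 was higher and 1 lower when adjusted over the list alone. PROK2, a ligand needed for the migration of GnRH neurons, had -22.9 ± 7.05 points (adjusted p = 0.0983 over all ends and 0.0311 over the list, Fisher's exact test). POMC, the precursor of ACTH and beta-endorphin, had 12.4 ± 6.11 points (0.145 and 0.0471), and it did not pass over the list on the spread between cytosines. The receptor gene PROKR2 had 13.9 ± 9.46 points. GNRH1, the gonadotropin-releasing hormone, was at 82.5% and 80.8% at the measured end on 5 cytosines. KISS1, the activator of GnRH neurons, had too few shared cytosines and was not analysed here.

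In GnRH signalling and intracellular calcium, 1 of 23 ends was higher and 0 lower, over all ends and over the list alone. Of 20 ends of steroid hormone synthesis and receptor genes, the coactivator gene NCOA3 was higher (12.9 ± 3.58 points, adjusted p = 0.045, Fisher's exact test), in a stretch shared with SULF2, and it was also the member past the threshold over the list alone. The body of ESR1, the estrogen receptor, was at 81.2% and 81.1% over 2893 cytosines (adjusted p = 0.736, Fisher's exact test), and its measured end at 69.9% and 73.0%.

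No end of the circadian clock (18 measured), photoreceptor and pinealocyte identity (21) or DNA methylation machinery (24) lists passed over all ends or over the list alone. The largest end differences among clock genes were 18.6 ± 7.59 points at CLOCK, 14.9 ± 7.45 at RORB and -14.1 ± 6.26 at ARNTL, in a stretch shared with BTBD10. Photoreceptor genes had -18.4 ± 6.99 points at ISL1, 17.1 ± 8.18 at CRX and 9.91 ± 7.0 at CNGB3. The methylation genes had -26.9 ± 9.17 points at DNMT3L, -10.9 ± 7.91 at MBD4, shared with IFT122, and -10.6 ± 7.42 at MBD2. PER2, a repressor in the clock, was at 86.5% and 87.5% in its body and 83.6% and 91.3% at its end. The methyltransferase DNMT3A was at 75.1% and 76.9% in its body, and its ends differed by 4.65 ± 5.08 and 7.63 ± 8.34 points. The demethylation enzyme TET1 was 2.62 ± 0.59 points higher in its body (83.3% to 86.0%, adjusted p = 1.13e-06, Fisher's exact test), below the minimum of 10 points and in a stretch shared with an uncharacterised gene. Its ends differed by 1.54 ± 5.82 and 2.5 ± 7.83 points.

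Markers of the cell types that a pineal sample could hold gave few calls. LUM, a proteoglycan of the extracellular matrix, was the member of 16 endothelial and mural ends that passed, and it passed over the list alone. It was 41.5 ± 11.6 points higher on 41 and 29 reads counted over 5 cytosines (adjusted p = 0.0122, Fisher's exact test). No end passed over all ends among neuronal (11 measured), astrocyte (12), oligodendrocyte (11), microglia and leukocyte (25) and erythroid (1) markers. The erythroid end, SLC4A1, had -14.6 ± 6.28 points and passed when adjusted over the list alone, which then holds 1 end. The measured ends of neuronal markers differed by at most 4.43 ± 7.17 points (GAD1), with 4.38 ± 6.01 at NEFM and -4.30 ± 6.28 at SYT1. Astrocyte genes had -13.5 ± 8.12 points at ALDH1L1, 11.4 ± 6.04 at AQP4 and 9.73 ± 7.42 at S100B, and oligodendrocyte genes 11.7 ± 7.40 at CNP, -6.71 ± 2.96 at MOBP and 3.97 ± 5.42 at OLIG2. Leukocyte genes had 12.8 ± 6.86 points at CX3CR1, -9.69 ± 4.96 at C1QC and 8.62 ± 4.68 at CD68.

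Imprinted genes (27 ends), developmental transcription factors (29) and GABA and glutamate receptors (31) had no end past the threshold, over all ends or over the list alone. Imprinted genes had -14.9 ± 6.12 points at MAGEL2, -11.3 ± 8.14 at DIRAS3 and 10.3 ± 8.38 at INPP5F. Developmental factors had 16.1 ± 7.79 at WT1 and 10.5 ± 6.90 at HOXA9. Receptor genes had -14.3 ± 9.29 at GABRA4, 11.3 ± 7.04 at GRM3 and -8.20 ± 5.55 at GRM4. In all 17 lists together, 4 of 333 ends were higher and 0 lower, and 8 were higher and 4 lower when adjusted over the list alone, of which 11 also passed on the spread between cytosines. None of 247 listed gene bodies reached 10 points with a passing test.

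No list stood apart from random genes of the same methylation level. The median difference of each list was set among 10000 random lists of the same size matched on methylation level, and 0 of 32 medians lay outside the central 95%, where 1.6 would by chance. For the 10 melatonin ends the central 95% ran from -4.34 to 5.32 points, so a small shift of such a list could not be seen. The highest gene-body medians were those of photoreceptor and pinealocyte identity (1.81 points, percentile 96.2), microglia and leukocyte markers (1.54 points, 95.6) and the circadian clock (1.37 points, 94.5). With coverage of at least 10 they fell to 1.28 points (81.77), 1.15 points (84.2) and 1.12 points (88.02) in the same order. The lowest percentile of a gene-body median was that of GABA and glutamate receptors (0.04 points, 7.95). The gene ends of melatonin synthesis had a median of 3.95 points (percentile 92.2), which was 0.15 points (43.84) with coverage of at least 10 and -0.39 points (32.08) with ends reaching 2000 bp outside the gene. With random lists matched on the number of cytosines instead of the level, 3 medians lay outside, those of the clock (percentile 99.07), photoreceptor (98.17) and GABA and glutamate receptor bodies (0.55). Of 35 ends of T lymphocyte markers, a list chosen after seeing the data, 0 passed over all ends or over the list alone.

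**Figure D4:**
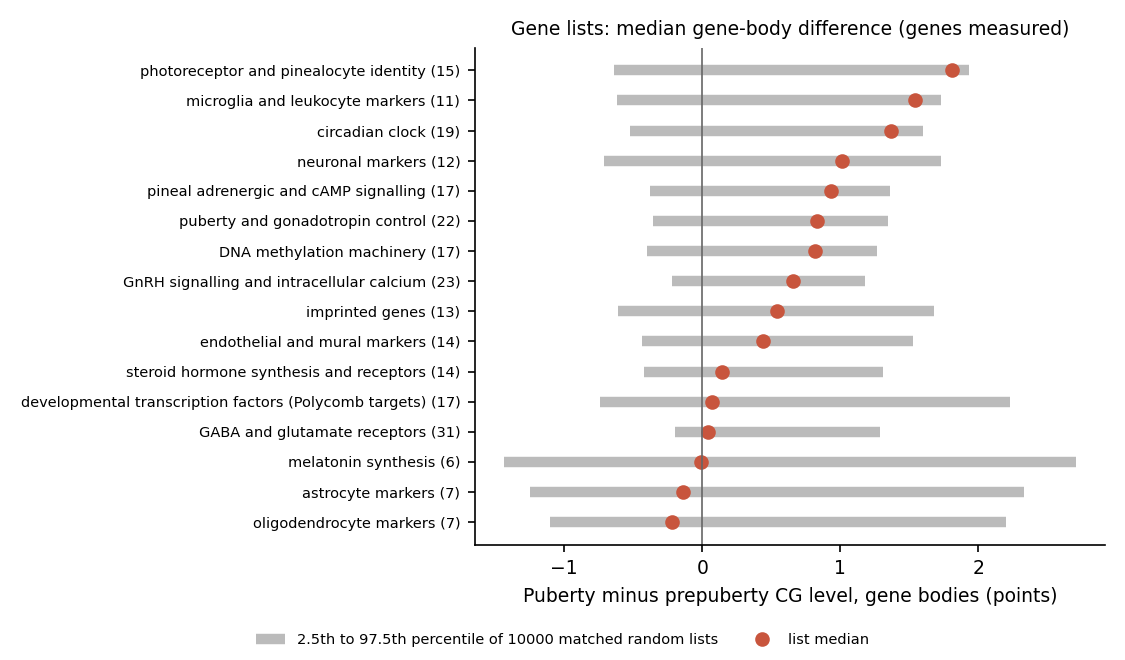
Median difference in CG level of gene bodies, puberty minus prepuberty in points (x axis), for each list with at least 3 measured bodies (y axis, number measured in brackets), with grey bars for the central 95% of 10000 matched random lists. All medians lie inside their bars, from photoreceptor and pinealocyte identity at 1.81 points down to oligodendrocyte markers at -0.22.

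Among 1 Mb stretches of the genome, the start of chromosome 21 differed most. The stretches described here were picked out after all of them had been measured. The mean difference of 2469 bins of 1 Mb was 0.32 points (SD 0.52), and 1887 of them were higher in the puberty library. The first bin of chromosome 21 was at 50.1% in the prepuberty library and 54.9% in the puberty library, 4.84 points higher. This part of the chromosome holds MKRN3, MAGEL2 and NDN, genes known as imprinted in other mammals, and part of SNURF, while the measured end of MAGEL2 itself was at 61.5% and 46.7%, not past the threshold. The largest decreases were on chromosome 4 at 6 to 7 Mb (74.2% to 70.7%, -3.55 points), with the endothelial nitric oxide synthase NOS3 and the potassium channel KCNH2 among its genes, and on chromosome 10 at 78 to 79 Mb (70.4% to 67.4%, -2.94 points), which holds 40 annotated V segments of an antigen receptor. Read depth also differed there. The ratio of puberty to prepuberty reads was 0.848 on chromosome 21, 1.25 on chromosome 4 and 1.20 on chromosome 10, against a median of 1.045 over all bins.

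**Figure D5:**
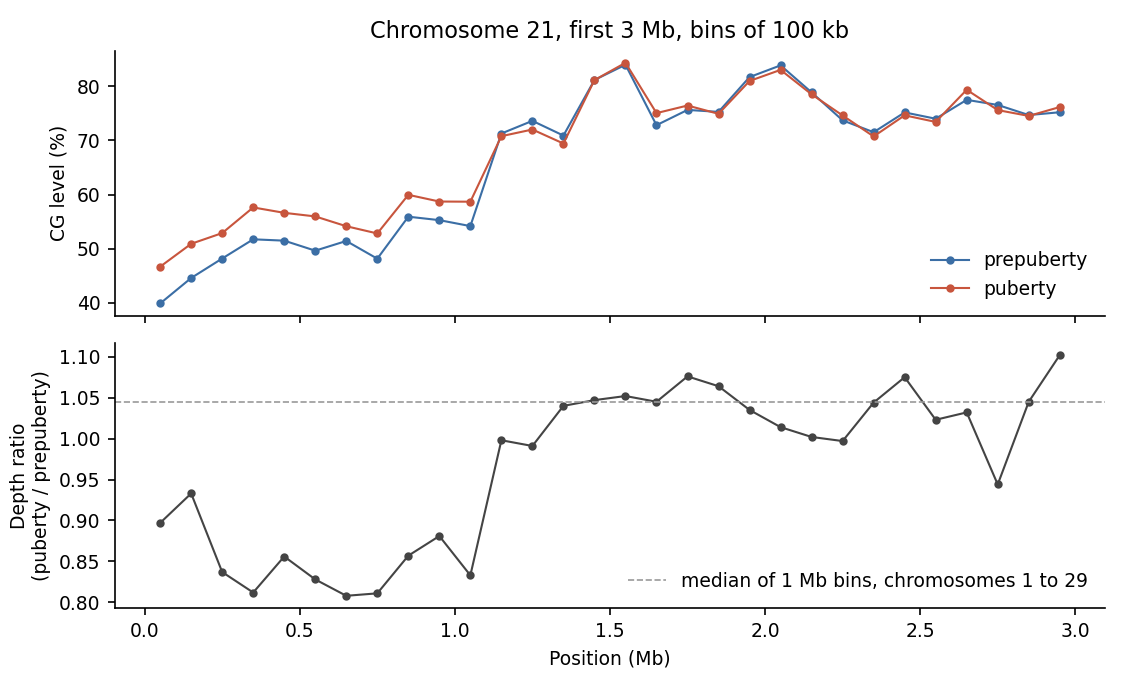
CG methylation level in percent (top, y axis not starting at 0) and ratio of puberty to prepuberty reads (bottom, dashed line at the median of all 1 Mb bins, 1.045) in bins of 100 kb along the first 3 Mb of chromosome 21 (x axis). In the first 11 bins the puberty level is higher by 2.73 to 6.80 points and the depth ratio is 0.808 to 0.933.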

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

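The equal-weight differences had been planned as alternatives. Their use to weigh explanations, and all other tests in this part, were chosen after the results were seen, as were the 3 patterns themselves, the limits that decided each test, the boundary of the chromosome 21 segment, the separate treatment of chromosomes 4 and 10, and the list of T lymphocyte markers. An earlier intention to weigh the photoreceptor and clock lists was given up because no list lay outside the range of random lists matched on methylation level, although both lay outside with matching on the number of cytosines.

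The comparisons use cytosines listed in both files, and outside them 1 kb windows with at least 20 CG cytosines listed in 1 library and at most 2 in the other drew attention. There were 43 such windows for the prepuberty library and 1274 for the puberty library, where the listed cytosines had a mean of 7.27 reads (6.74 in the former). On the mitochondrial sequence, 33 CG cytosines were listed in the prepuberty library and 24 in the puberty library.

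The CG level was higher in the puberty library on all 29 chromosomes. Unconverted cytosines in the puberty library would have had to bring the difference over shared cytosines to 0 after correction for error rates, and it stayed at 0.333 points. At levels of 80.5% and 80.9%, error rates of 0.416% and 0.675% can move the difference only slightly, so the rates fixed this outcome. It argues against unconverted cytosines as the whole cause only if these rates, inferred from the deposited p-values, hold. The conversion rate itself was not given. Correction and equal weights together left 0.164 of 0.382 points, with 27 of 29 chromosomes higher, so error rates and depth jointly could account for part of it. With equal weights the difference between genes was 0.016 points, but in gene bodies 0.389 points of 0.503 remained. Equal weights also shift weight towards cytosines with few reads, and the depth ratio was alike between genes (1.048) and in gene bodies (1.044). With coverage of at least 10, the difference between genes was 0.174 of 0.205 points. In 1 kb windows classed by listed CG cytosines, the classes starting at 1, 40 and 80 had depth ratios of 1.005, 1.093 and 1.195. Their differences were 0.23, 0.45 and 2.32 points, so depth ratio and difference rose together with the density of listed CG cytosines. Uneven read depth thus stays possible but undecided as a cause of the difference between genes. The classes were not split by feature, so depth that varies with CG density stays undecided for gene bodies too. With 1 library per group, sexual maturation cannot be told apart from differences between the animals or libraries.

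The first 1.1 Mb of chromosome 21, with MKRN3, MAGEL2 and NDN, was 4.81 points higher in the puberty library, and 11 of 11 bins of 100 kb were higher, although the measured end of MAGEL2 had -14.9 points and did not pass its test. The stricter calling rule of the puberty file is argued against, since the matched rule left 4.739 points. A candidate explanation is a different number of copies of the segment in the libraries, as the depth ratio of the first 1 Mb, 0.848, lay outside the central 95% of bins (1.016 to 1.098). The segment had a mean of 21.2 reads in the prepuberty and 18.0 in the puberty library, against 16.6 and 17.2 in the next 19 bins. Depth was thus above that of its neighbours in both libraries, and more so in the prepuberty library. A low depth ratio did not always go with a higher level, since the bin with the lowest ratio (0.785, chromosome 17 at 60 to 61 Mb) differed by 0.4 points. A general difference at partly methylated sequence cannot be told apart from it, because the 67 other bins at 40 to 60% were also higher on average (1.51 points, SD 2.37, against 0.32 over all bins) while 3 of them (4.5%) reached the segment's median of 4.70 points.

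The bins on chromosome 4 (6 to 7 Mb) and chromosome 10 (78 to 79 Mb) were lower in the puberty library and had the highest and the next highest depth ratios of 2469 bins. Extra copies, or reads of related sequence, in the puberty library cannot be told apart from other causes in either bin. The 10 kb windows of ordinary depth ratio (0.868 to 1.28) kept -1.65 of -3.59 points on chromosome 4 and -2.82 of -2.90 on chromosome 10, with -4.98 and -2.37 points in windows above that range, but the range includes the ratios of the bins themselves (1.254 and 1.198) and so need not leave such windows out. A larger share of lymphocytes in the puberty sample could lower these bins, but T lymphocyte marker gene bodies lay at percentile 16.39 of random lists (median 0.13 points over 23 bodies), which leaves it undecided. For these bins and for the chromosome 21 segment, the stage of the animals stays open as an untested explanation.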

How the results depend on the processing

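The matched calling rule, the error-rate corrections, the deep non-CG cytosines, the spread test without a minimum difference, the thinned lists and single strands were chosen after seeing the data. No paired analysis was possible because each group has 1 library. The cause of a change was not tested unless given. The higher CG level in the puberty library kept its direction under the alternatives run, over all listed cytosines from 0.248 points (unweighted) and 0.253 (thinned to 5 reads) to 0.484 (coverage of at least 10), with 0.362 on chromosomes 1 to 29 only, 0.382 for shared cytosines, 0.337 under the matched rule and 0.357 corrected for error rates, while over shared cytosines it was 0.211 unweighted and 0.164 unweighted and corrected, with 27 of 29 chromosomes higher in the latter. A coverage minimum of 1 changes nothing, as no listed cytosine has under 5 reads. The CHG difference was 8.548 points (coverage of at least 10), 8.399 (chromosomes 1 to 29), 2.299 (shared), 9.131 (unweighted), 9.103 (thinned) and 8.292 (corrected), and reversed to -0.235 under the matched rule. The CHH difference was 5.344, 5.849, 2.91, 6.746, 6.771 and 5.739 points in the same order, and 0.646 under the matched rule. The ratio of listed CHG and CHH cytosines was 0.6697 and 0.7137 with coverage of at least 10 and 0.3657 and 0.4545 under a level of 30%, and reversed to 1.1712 and 1.1926 under the matched rule and 1.1122 and 1.0902 with at least 20 reads and a level of 30%, where deep CG cytosines had a ratio of 1.066. By its construction the matched rule removes weakly methylated cytosines from the prepuberty file. In gene bodies the difference was 0.483 (coverage of at least 10), 0.389 (unweighted), 0.488 (all cytosines of each library), 0.461 (corrected), 0.347 (unweighted and corrected) and 0.49 points (matched rule). Between genes it was 0.174, 0.016, 0.266, 0.155, -0.032 (reversed) and 0.191 in the same order, and at gene ends 0.316 unweighted and corrected. Windows past the threshold numbered 3886 (coverage of at least 10), 1130 (double the cytosines), 18859 (no minimum difference), 1057 (at least 30 points), 831 (spread between cytosines), 3349 (thinned) and 3293 (2000 bp windows) against 6944. Gene ends numbered 98 (coverage of at least 10), 6 (at least 30 points), 7 (spread), 32 (thinned) and 230 (2000 bp outside to the end) against 150. Gene bodies numbered 21 (coverage of at least 10, 18 higher), 8 (double the cytosines), 1770 (no minimum), 0 (at least 30 points), 25 (spread), 773 (spread, no minimum) and 556 (the same, thinned) against 42, and 19 when thinned, with the balance reversed. Counts of single cytosines stayed within 1.5 times 24650 under the alternatives run. Of the 33 named regions past the threshold, 12 were kept by the spread test, 11 after thinning, 10 of 16 measured with coverage of at least 10, and 33 under the matched rule and without the top 1% of coverage, and none reversed. Of named regions not past it, the end of SYT1 reversed to 3.84 (coverage of at least 10) and 0.53 points (thinned), the body of ESR1 to 0.14 and an end of TET1 to -1.05 (coverage of at least 10), and an end of DNMT3A to -1.69 (thinned), while the end of TPH1 passed with coverage of at least 10 (28.92 points). List medians outside the central 95% numbered 3 with matching on cytosine number (clock, percentile 99.07, photoreceptor, 98.17, and GABA and glutamate receptor bodies, 0.55), 2 with 2000 bp ends (adrenergic, 99.29, and imprinted, 1.29), 1 thinned (photoreceptor bodies, 98.72) and 1 on each strand (plus, leukocyte bodies, 99.89, and minus, melatonin ends, 99.45 with 5 measured, against 18.44 and -3.57 points with 3 measured on the plus strand). Depth limits what could be found: of simulated decreases of 20 points, drawn without the listing rule, 23.5% were found in windows and 53.5% at gene ends, and of 10 points at gene ends 11.5%.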

Other observations

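The test behind these values, on the spread between cytosines with no minimum difference, was chosen after the data were seen. In simulated data with independent cytosines it called more unchanged gene bodies (68 of 12848) without thinning than after it (9). It is a normal approximation that treats cytosines as independent, although neighbours can share reads. It compares these libraries only, and the genes were chosen after their values were seen. Of 245 listed gene bodies, 14 passed it, 13 higher and 1 lower in the puberty library, a share like that of all bodies (773 of 13480, 685 higher and 88 lower). RORA, a nuclear receptor of the circadian clock on chromosome 10 (53430022 to 54233980), was at 78.2% and 80.6%, 2.43 ± 0.26 points higher (adjusted p = 2.1e-16, n = 4728 cytosines), and ranked 1 of 13480 bodies by this p-value, which many cytosines make small, not by size. ARNTL, which encodes the clock activator BMAL1, was 3.75 ± 0.86 points higher (adjusted p = 0.00122, n = 560 cytosines). SLC17A6, a vesicular glutamate transporter, was 6.74 ± 1.42 points higher, ITPR1, a calcium channel of the endoplasmic reticulum, 2.37 ± 0.41, and the mineralocorticoid receptor NR3C2 1.38 ± 0.21. NR3C2 had fewer reads in the puberty library (98446 and 81555, ratio 0.828, against a median of 1.045 over bins of 1 Mb) and lies partly in the bin with the lowest depth ratio. ADCY2 (1.45 ± 0.35), the coactivators NCOA1 (1.51 ± 0.41) and NCOA2 (1.42 ± 0.33), TET1 (2.62 ± 0.59), the glutamate transporter SLC1A2 (2.30 ± 0.64), the microglial receptor P2RY12 (2.77 ± 0.77), the GABA-B receptor subunit GABBR2 (1.29 ± 0.39) and the calcium channel CACNA1C (1.34 ± 0.42) were also higher. After thinning both libraries to the smaller coverage, 11 of the 14 still passed, and NCOA1, P2RY12 and GABBR2 did not.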
